A study of Physcomitrium patens with 3 samples.

How the data were processed

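Small RNA was sequenced from protonemata, the filamentous young tissue of the moss Physcomitrium patens, in 3 genotypes: wild type, rdr2 and rdr6. Per the labels' protocols, the tissue was 10 days old, was grown on cellophane over agar medium at 22 °C with 16 h of light and 8 h of dark, and total RNA was extracted with Tri-Reagent before libraries were made for the Illumina GAII. There was 1 library per genotype.

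Per the file headers, each deposited table pairs a distinct sequence, called a tag here, with the count of its reads. The values are raw counts: whole numbers whose totals differ between libraries. Tags were 15 to 30 nt long in all 3 tables. Adapter removal, the length limits and any filter are not given in the sources used here. The tables hold every kind of short RNA, including pieces of rRNA and tRNA.

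Counts were divided by the total of their own table to give RPM, the usual scale for small RNA reads. A mutant was compared with wild type as a ratio of RPM with an exact 95% interval, which conditions on the sum of both counts (conditional binomial, Clopper-Pearson). Shares of reads have exact Clopper-Pearson 95% intervals. Reads had no molecular identifiers, so all intervals and floors cover counting error only. With 1 library per genotype no difference has a replicate check, no p-value is given, and every comparison describes these libraries. A ratio against 0 reads is given against 3 reads in place of 0, with the limit of its exact interval. Medians of tag ratios by length are given with counts under 3 set to 3 where stated. A difference between genotypes and any other difference between the libraries cannot be separated in this design. Whether each library carries the mutation its label names could not be read from small RNA tags.

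No reference genome was used. TAS3 loci, genome windows, annotated RDR genes and the share of reads that match the moss genome are therefore not analysed here. In place of windows, single tags were called lower or higher by the rule of size set for windows: at least 30 reads over the 3 libraries, a ratio of at least 4-fold, and an interval that excludes 2-fold. Tags were counted in 2 classes, 23-24 nt and 20-22 nt. Counting the 30 reads over 3 libraries favours tags present in the other mutant, so the rule was also run on tags with 30 reads in wild type and the mutant together. Counts of tags are not counts of loci, since several tags can come from one place.

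Pieces of long RNAs were set apart by a rule chosen after seeing the data. A tag of 20-24 nt was called fragment-like when longer tags that contain it, of 25 nt or more, had reads equal to at least 0.05 of its own, or when it ended in CCA as mature tRNAs do. Other tags of 20-24 nt are called not fragment-like. The rule also removes true siRNA tags that overlap longer reads, and it keeps degradation products seen too rarely to have a longer partner.

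Reads of 19 to 23 nt were assigned to a miRNA family when they aligned without gaps to its sequence with at most 2 mismatches over at least 18 nt, at an offset of at most 2 nt. The closest family was taken and ties were left out. The list of 15 moss families and a list of 15 families known from flowering plants were set before the data were examined. Their sequences came from general knowledge, so a family without reads is not shown to be absent. Families were named when they had at least 30 reads over the 3 libraries. For a family, higher or lower means at least 2-fold with an interval that excludes 1.

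Scaling was checked on the 1406 tags of 21 nt that were not fragment-like and had at least 30 reads. Their median log2 ratio to wild type, with 0.5 reads added to each count, was 0.60 for rdr2 and 1.07 for rdr6. These shifts, 1.52-fold and 2.09-fold, are the level against which changes relative to the median 21 nt tag are given. This scale centres 21 nt tags on themselves, so it does not test a change of that class as a whole.

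Without a genome, the rule for named tags set beforehand was the 10 tags per direction with the ratio bound farthest from 1, among tags with at least 100 reads. Over all 18045 such tags, that rule took 40 places in the 2 mutants and 2 directions, all held by fragment-like tags or tags outside 20-24 nt, and 32 of them did not reach 10 RPM in 2 libraries. Such tags can come from another organism and are not printed. The rule was therefore repeated on tags of 20-24 nt that were not fragment-like and reached 10 RPM in at least 2 libraries, a limit chosen after seeing the data. Without the RPM limit, all 10 leading higher tags of this class in each mutant fell short of it. Of the 10 leading lower tags, 1 did in rdr2 and 0 did in rdr6. The named higher tags are therefore those left after the top-ranked ones were dropped.

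Tags lower in rdr6 than in both other libraries were joined where they overlapped by at least 12 nt on either strand, beginning with the most abundant, and regions of at least 10 tags were kept. The rule of size was tested on simulated data for all 3017 tags that were not fragment-like. With 200 tags lowered 20-fold it called 78.5% of them in rdr2 against wild type and 85% in rdr6 against wild type. With 8-fold it called 63.5% and 67%, and at most 1 unchanged tag was called in any run. The simulated counts varied by Poisson counting error alone, so they give no rate of false calls between real libraries.

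Alternatives set beforehand were the moss miRNA reads as the denominator, leaving out tags seen once, wider length classes, 0 or 3 mismatches for miRNAs, at least 100 reads, and a 2-fold rule. Those added after seeing the data were tags that are not fragment-like for the length classes, fragment-like tags kept for the tag counts, a fragment share of 0.2, scaling to the median 21 nt tag, the miRNA denominator without miR535, a level of 1 RPM in at least 2 libraries, and tags chosen and marked on the reads of wild type and the mutant alone. Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9 were used.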

Results

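Small RNA libraries were compared between wild-type protonemata of the moss Physcomitrium patens and the mutants rdr2 and rdr6. RDR2 and RDR6 are RNA-dependent RNA polymerases, which copy single-stranded RNA into the double strands from which siRNAs are cut. In plants RDR2 is known for siRNAs of repeats and RDR6 for trans-acting siRNAs, whereas miRNAs come from hairpins and need neither. The tables held 8523003 reads of wild type, 7440625 of rdr2 and 9222916 of rdr6, from 1308936, 1053849 and 1140309 distinct tags. There was 1 library per genotype, so the intervals are exact 95% intervals for counting error only and no difference was tested against a spread between replicates.

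The first question was how the length classes of small RNA differed between the wild-type library and each mutant library. As shares of all reads, the 23-24 nt class was smaller in rdr2 and the 21 nt class larger in both mutants. The denominators include rRNA ends of bacterial type, described below, which differed between the libraries. A 5S rRNA end of that type made up 12.9% of reads in wild type, 0.0272% in rdr2 and 0.546% in rdr6. A 23S rRNA end made up 4.23%, 0.00571% and 0.185%. Such reads lower the wild-type share of other reads, so a ratio above 1 may come in part from them. Reads seen nearly only in 1 library were also common in rdr2. Tags with at least 100 reads that stood at least 50-fold above both other libraries held 9.07% of wild-type, 9.36% of rdr2 and 1.40% of rdr6 reads. Of the 23-24 nt reads they held 8.02%, 8.02% and 1.89%. Their source was not determined. Reads of 23-24 nt made up 16.4% of the wild-type library (16.37% to 16.42%), 11.4% of rdr2 and 13.8% of rdr6. The RPM ratio to wild type was 0.696 in rdr2 (0.694 to 0.697) and 0.844 in rdr6 (0.842 to 0.846). Per moss miRNA read it was 0.851 and 0.281, or 0.938 and 0.748 with miR535 left out of that denominator. Scaled to the median 21 nt tag it was 0.458 and 0.403. Reads of 21 nt made up 17.8% of wild type, 22.3% of rdr2 and 33.8% of rdr6, which gave ratios of 1.26 (1.254 to 1.260) and 1.90 (1.900 to 1.907). Per moss miRNA read they were 1.54 and 0.633, and 1.70 and 1.69 when miR535 was left out of that denominator but kept among the 21 nt reads. The main miR535 tag alone stood at 49474 RPM in wild type and 188144 RPM in rdr6, against 177528 and 337905 RPM for all 21 nt reads. Much of the larger 21 nt total in rdr6 was therefore this tag. Scaled to the median 21 nt tag the ratios of 21 nt reads were 0.827 and 0.910, but that scale comes from the same class and cannot test its direction. Among reads of 20-24 nt alone, the 23-24 nt share was 34.0% in wild type, 24.7% in rdr2 and 23.1% in rdr6.

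Pieces of longer RNAs filled much of these classes, and more so in wild type. Fragment-like tags held 64.4% of the 20-24 nt reads in wild type, 51.2% in rdr2 and 40.5% in rdr6. Among the remaining tags, 23-24 nt reads stood at 2.32% of the library in wild type, 1.25% in rdr2 and 3.17% in rdr6. The rdr2 ratio was then 0.540 (0.536 to 0.545), while the rdr6 ratio turned from below 1 to 1.37 (1.358 to 1.374). Remaining 21 nt reads stood at 12.1%, 17.8% and 29.1%.

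**Figure D1:**
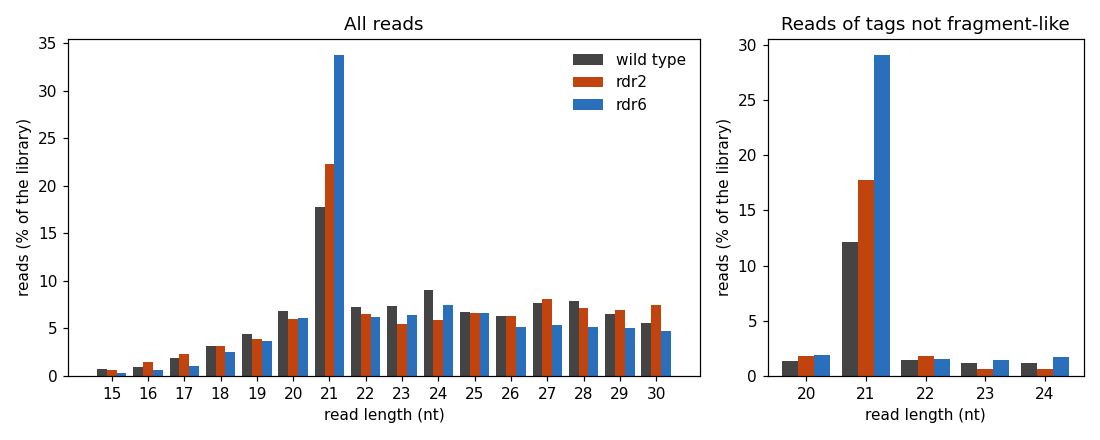
Reads of each length (x axis, nt) as a percentage of the library's reads (y axis), for the 3 libraries, over all reads (left) and over 20-24 nt tags that are not fragment-like (right). Each bar is 1 library. The 21 nt bar is highest in rdr6, at 33.8% of all reads, and on the right the 23 and 24 nt bars are lowest in rdr2.

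In rdr2, most single tags of 23-24 nt that were not fragment-like were lower than in wild type. Of the 914 tags of 23-24 nt that were not fragment-like and had at least 30 reads, 594 were lower by the rule of size (65.0%) and 16 were higher. In rdr2, 266 of the 446 tags of 23 nt and 291 of the 468 tags of 24 nt had no read. With counts under 3 set to 3, which makes these ratios bounds, the median log2 ratio was −2.22 at 23 nt and −2.13 at 24 nt, against 0.60 at 21 nt. All reads of these tags together gave a ratio of 0.250 at 23 nt (0.241 to 0.258) and 0.297 at 24 nt (0.286 to 0.307). Chosen on wild-type and rdr2 reads alone, 237 of 312 tags were lower, and 225 of the 237 stood in rdr6 at 0.5 times the wild-type level or more. The 581 tags that were lower in rdr2 than in both other libraries held 25338 reads in wild type, 401 in rdr2 and 51389 in rdr6, a 55.2-fold lower RPM in rdr2 than in wild type (50.0 to 61.0). Because these tags were picked as lower, that fold overstates the change of the class. Over all tags, including fragment-like ones, 2818 of 9557 were lower and 719 higher.

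The leading rdr2-lower tags were 8 tags of 23 nt, 1 of 24 nt and 1 of 21 nt. TCCTGCTGGAGATTTTGAATGGC had 489 reads in wild type, 2 in rdr2 and 1010 in rdr6, a ratio of 0.00468 (0.000566 to 0.0170). ATGTAGAAGTCATAGACGGACGAC had 426, 2 and 730 reads, a ratio of 0.00538 (0.000649 to 0.0195). TGGAATGGGACACTATCGATGGC had 205 reads in wild type and 0 in rdr2, 59.7-fold lower against 3 reads and at least 48.1-fold by the exact interval. TGCAGAACCAGAAAGTAGAGTGC had 164 and 0 reads, 47.7-fold lower against 3 reads and at least 38.4-fold by the interval. The 21 nt tag AGAAGCTATCGTCGAACCGGC, at 143 and 0 reads, lies within the 23 nt tag TAAGAAGCTATCGTCGAACCGGC, at 145 and 0 reads. The other named tags were TCCATGTAGAAGTCATAGACGGA, TCAGAGATGCAGGATTGTACGCC, TCGAACCTGGATAGCGACATACT and AGAAGGCATTCTGGGACTGTACT, with 249 to 142 reads in wild type and at most 1 in rdr2.

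**Figure D2:**
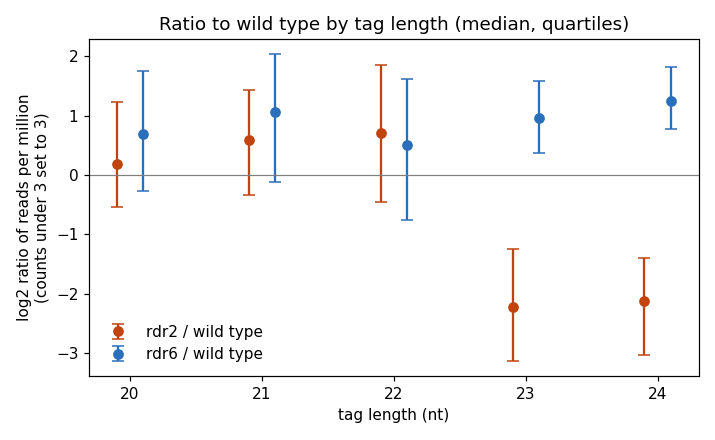
Log2 ratio of RPM to wild type (y axis) by tag length (x axis, nt) for rdr2 and rdr6, with counts under 3 set to 3. Points are medians and bars the quartiles over tags that are not fragment-like and have at least 30 reads. The rdr2 medians are −2.22 at 23 nt and −2.13 at 24 nt, where most tags have no rdr2 read and the ratios are bounds, and lie between 0.20 and 0.71 at 20 to 22 nt. The rdr6 medians lie between 0.52 and 1.25 at the 5 lengths shown.

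Of the 2103 tags of 20-22 nt that were not fragment-like, 89 were lower in rdr2 and 291 higher. Per moss miRNA read, the counts were 69 lower and 361 higher. Scaled to the median 21 nt tag they were 160 and 162, but 1406 of these tags set that scale, which evens the balance. With fragment-like tags kept, 2016 of 12559 were lower and 1227 higher, so the balance of directions rests on the tags counted. Among tags not fragment-like that had 1 RPM in at least 2 libraries, 78 of 1773 were lower and 181 higher. Among the named tags higher in rdr2, GACTGTAGAAACACCTGAAGC rose from 523 RPM in wild type to 5180 RPM, a ratio of 9.90 (9.60 to 10.21), and stood at 1811 RPM in rdr6. It aligns over 19 nt with 2 mismatches to the strand opposite miR537. TTTGCGCGTGAATTTGAAGGC rose from 3224 to 18824 RPM, a ratio of 5.84 (5.76 to 5.91), and was 1.20 times wild type in rdr6. CTCTCCCTCAAAGGCTTCCAA had the bound farthest from 1, with a ratio of 17.9 (14.97 to 21.7). Others were TCCAAGCACTTATCGCACCCTG at a ratio of 11.2, TTCGATAAAATGGCAGAATCC at 11.9, ATGGATTGCCTAAGAGAGACG at 12.2 and TAGCCTATGATGCAGATTCTTC at 7.38. ACGAAGGTCTGCATCATAGC and TCTTGTCAATGTTTAGGGGC had ratios of 5.17 and 5.22.

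In rdr6, a limited set of 20-22 nt tags and few 23-24 nt tags were lower among those that were not fragment-like. Of the 2103 tags of 20-22 nt, 244 were lower (11.6%) and 431 were higher. The 223 tags of 20-22 nt lower in rdr6 than in both other libraries held 157005 reads in wild type, 248685 in rdr2 and 24858 in rdr6, 6.83-fold lower in rdr6 RPM than in wild type (6.74 to 6.93). A single tag, TGGCATTGTAGGTTTAAGAGC, held 65.0% of these wild-type reads and 95.1% of the rdr6 reads, and the other 222 tags together were 48.8-fold lower (46.1 to 51.6). As these tags and the regions below were picked as lower, their folds overstate the change of the class. Lower tags made up 18.1% of tags at 22 nt, 10.6% at 21 nt and 7.27% at 20 nt. Of the 914 tags of 23-24 nt, 27 were lower and 117 higher. Scaled to the median 21 nt tag, the 20-22 nt counts became 348 lower and 108 higher, and the 23-24 nt counts 42 lower and 18 higher. With fragment-like tags kept, 1887 of 12559 tags of 20-22 nt were lower and 841 higher, and 1356 of 9557 tags of 23-24 nt were lower and 554 higher. Among tags not fragment-like that had 1 RPM in at least 2 libraries, 22 of 770 tags of 23-24 nt were lower and 53 higher. At 20-22 nt, 231 of 1773 such tags were lower and 309 higher. The 23-24 nt tags lower in rdr6 than in both other libraries numbered 17, and 16 of them shared at least 15 nt with a 20-22 nt tag that was also lower.

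The leading rdr6-lower tags were 7 of 21 nt and 3 of 22 nt. AGGCAGTAGAAGAGCACCGGA had 11185 reads in wild type, 14098 in rdr2 and 83 in rdr6, 146-fold lower in rdr6 RPM than in wild type (118 to 183). TGGGCAAGGCAGTAGAAGAGC had 3433, 8390 and 25 reads, 149-fold lower (100.5 to 230). AAGGCAGTAGAAGAGCACCGGA was 96.5-fold and AAGGCAGTAGAAGAGCACCGG 107-fold lower, and CAAGGCAGTAGAAGAGCACCG fell from 440 reads to 3. AGGCAGTAGAAGAGCACCGGAC, with 262 reads in wild type and 0 in rdr6, was 94.5-fold lower against 3 reads and at least 76.3-fold by the exact interval. TCCTGTATCGGTTGTATATCAC had 625 and 4 reads, AGGAGTGTTGCATTCAAATGC 1442 and 15, TAGGAATATCTCTAAAGCCCT 305 and 1, and AGGAGACACGCAGACACGCGC 393 and 2.

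Many of these tags came from few stretches of sequence. Of the 240 tags lower in rdr6 than in both other libraries, 127 joined into 6 regions of 35 to 75 nt. The ends of 3 regions overlapped, by 9 and 11 nt, and tags crossed both junctions: 139 and 177 reads in wild type, 96 and 211 in rdr2, 1 and 6 in rdr6. The joined region was 142 nt long: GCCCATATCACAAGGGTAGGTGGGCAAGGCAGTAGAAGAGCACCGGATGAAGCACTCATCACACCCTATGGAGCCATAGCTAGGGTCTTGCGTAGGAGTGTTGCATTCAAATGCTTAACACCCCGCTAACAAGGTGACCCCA. Its place in the genome is not analysed here. Tags of 20-24 nt that match it exactly had 50319 reads in wild type, 69776 in rdr2 and 664 in rdr6. The RPM was 82.0-fold lower in rdr6 than in wild type (76.0 to 88.7) and 1.59 times wild type in rdr2. Both strands gave reads, 84.7% forward and 15.3% reverse in wild type, and 94.6% of the wild-type reads were 21 or 22 nt long. The reads stood in 2 blocks, led by AGGCAGTAGAAGAGCACCGGA at positions 27 to 47 and by TAGGAGTGTTGCATTCAAATGC at 93 to 114, which had 8728, 11431 and 177 reads. The reverse tag CGGTGCTCTTCTACTGCCTTG, at 25 to 45, had 2240, 3731 and 35 reads.

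**Figure D3:**
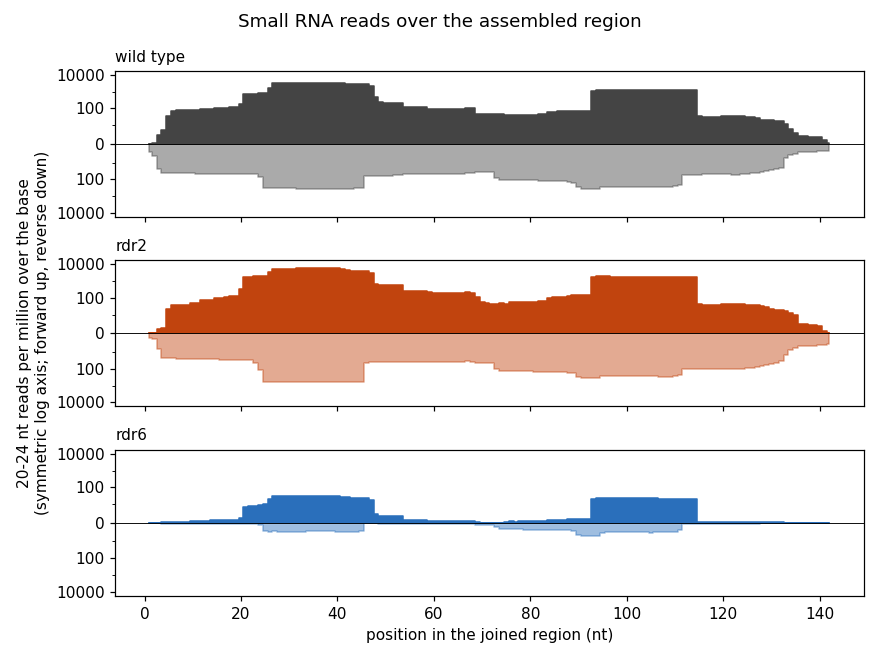
RPM of 20-24 nt reads over each base (y axis, symmetric log scale, forward strand up and reverse strand down) along the joined 142 nt region (x axis, nt), in 1 panel per library. Reads cover both strands in wild type and rdr2, with peaks at positions 27 to 47 and 93 to 114. In rdr6 only low peaks remain at those places, 664 reads in all against 50319 in wild type.

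A separate region of 72 nt, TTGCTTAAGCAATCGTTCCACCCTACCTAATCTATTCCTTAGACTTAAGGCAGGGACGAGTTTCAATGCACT, had 1620 reads in wild type, 2154 in rdr2 and 31 in rdr6, 56.5-fold lower in rdr6 (39.7 to 83.5). A region of 45 nt, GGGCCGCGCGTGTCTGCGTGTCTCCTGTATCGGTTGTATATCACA, had 2977, 3757 and 52 reads, 62.0-fold lower (47.1 to 83.1). A region of 35 nt, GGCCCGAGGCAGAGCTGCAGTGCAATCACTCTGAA, had 884, 468 and 10 reads, 95.7-fold lower (51.8 to 200.2).

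Named tags higher in rdr6 were all 21 nt long, with ratios from 10.2 to 22.8. TGACAACGAGAGAGAGCCCGC, at 1 mismatch from the main miR535 tag, had a ratio of 22.8 (20.8 to 24.9). The main tag, with far more reads, was itself 3.80 times wild type, and misread copies of it were not told apart from this tag. TCGGACCAGGCATCATTCCTT, at 3 mismatches from miR166, a family that targets HD-ZIP III transcription factors, had a ratio of 18.9 (13.8 to 26.7). GAGCTGTTCAGACTCTGAGAG, at 4 mismatches from miR533, had 14.4 (12.4 to 16.9), and GAGCTGTTCAGACTCTGAGAC had 16.4. Ratios were 21.1 for TGCGAGAAGTCAGAGACAGTC, 16.8 for TTGAAGGAGTTCATTGGTATA and 10.8 for TTGTAGAGTCACGCACCTCTG. They were 10.2 for TTGTAGAGTCATGCACCTCTG, 11.6 for AGAAGCCTTTGTGGGAGAGGA and 12.01 for TTCGATAAAATGGCAGAATCC, which was higher in rdr2 too. All 10 stayed above wild type when scaled to the median 21 nt tag. That scale divides by 2.09, so tags picked at these ratios could not fall below 1.

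The mutants' calls were compared within each length class. At 23-24 nt, 7 tags were lower in both mutants, where independent lists would share 17.5, and at 20-22 nt 14 were, against 10.3. The limit of 30 reads over the 3 libraries favours tags present in the other mutant, so a shortfall of shared lower tags can come from it. With the 30 reads counted in wild type and rdr2 together, 312 tags of 23-24 nt were tested in place of 914. Tags higher in both numbered 3 at 23-24 nt, against 2.05, and 56 at 20-22 nt, against 59.6. Simulated libraries without any effect shared, in each class, 0 lower and 0.01 higher tags on average, but they held at most 1 called tag at 23-24 nt and 2 at 20-22 nt, so they give no measure for lists of this length. The wild-type library could not be split, so part of any overlap may rest on it.

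miRNA families, which serve as a comparison because they are made without an RDR, gave 7.50% of reads in wild type, 6.13% in rdr2 and 22.6% in rdr6. The ratio to wild type was 0.818 in rdr2 (0.815 to 0.821) and 3.01 in rdr6 (3.0004 to 3.017). A single family set the rdr6 value: miR535 rose from 53813 to 201691 RPM, 3.75-fold (3.74 to 3.76), and the other families together had a ratio of 1.13. Of the 15 listed families, 12 had at least 30 reads. In RPM, 7 were higher in rdr6 and none was lower. Relative to the median 21 nt tag none was higher and 3 were lower, so no direction that all families share holds under both scalings.

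In rdr6, miR156, which targets SBP-box transcription factors, was 3.41 times wild type (3.30 to 3.52), miR160, a regulator of auxin response factors, 4.12 times (3.28 to 5.23), and miR390, which directs the cutting of TAS3 transcripts, 2.27 times (2.16 to 2.38). miR408 was 2.78 and miR537 3.65 times wild type. miR533 was 4.11 times wild type, but 0.637 times when only reads without a mismatch were counted. miR166 was 0.956, miR319 1.03, miR534 0.876, miR529 1.49 and miR536 1.14 times wild type. Relative to the median 21 nt tag, miR166, miR319 and miR534 were 2.19-fold, 2.04-fold and 2.39-fold lower.

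In rdr2, miR537 alone passed 2-fold, at 7.43 times wild type (6.78 to 8.15), and it stayed 4.89 times wild type relative to the median 21 nt tag. Its main tag, TTGAGGTGTTTCTACAGGCTA, was also among the named higher tags, at 6.67 times. miR166 was 0.558 (0.531 to 0.587), miR408 0.511 (0.328 to 0.780), miR319 0.644 and miR390 0.733 times wild type, and these 4 were more than 2-fold lower relative to the median 21 nt tag. miR535 was 0.848, miR529 0.814, miR156 1.17, miR160 1.27 and miR536 1.67 times wild type. miR533 was 1.58 times and miR534 1.01 times wild type, but 0.671 and 1.72 times when only reads without a mismatch were counted.

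Reads of families known from flowering plants were scarce in all 3 libraries. They numbered 9 in wild type (1.06 RPM), 33 in rdr2 (4.44 RPM) and 24 in rdr6 (2.60 RPM). miR159, a close relative of miR319 in sequence, held 9, 19 and 22 of these reads, and 13 of the rdr2 reads were assigned to miR158. With no mismatch allowed, these families stood at 0 RPM in wild type, 2.82 in rdr2 and 0.108 in rdr6. Exact matches were therefore nearly all in rdr2, and their source was not determined.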

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

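All tests in this part were chosen after the results they bear on had been seen. Each library held rRNA ends of bacterial type, recognised by short patterns of rRNA ends written from general knowledge and from the abundant tags. They lie outside the comparisons of genotypes, and in both mutants a form of them stood above wild type. A bacterial-type 16S rRNA start reached 969 RPM in rdr2 (946 to 991) against 1.53 RPM in wild type. A bacterial-type 23S rRNA end reached 5265 RPM in rdr6 (5218 to 5312) against 4.69 RPM in wild type.

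The wild-type library held other forms. A bacterial-type 5S rRNA end made up 12.9% of its reads and 0.0272% of those of rdr2, which is 473-fold higher in wild type, and stood at 0.546% in rdr6. The tables argue against a matching rise in breakdown of moss cytosolic rRNA in wild type. The moss 5.8S rRNA start was lower there, at 0.634 times its rdr2 level. The moss 18S rRNA start stood at 80.0 RPM against 65.6 RPM in rdr2, far from a 473-fold difference. Both starts are of cytosolic rRNA, so they do not bear on RNA of moss chloroplasts or mitochondria. RNA of another organism, in the cultures or added during library work, is a candidate source. It stays open, and moss organelle RNA was not told apart from it, as the tags were not matched to any genome. No biological explanation by genotype was tested. These reads count in the denominators, so all-read ratios to wild type carry them.

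The fall of 23-24 nt tags in rdr2 was set against 3 technical explanations. Depth or dilution would lower shorter tags alike, but the median log2 ratio of 20-22 nt tags was 0.60 for those not fragment-like and 0.06 with fragment-like tags kept. A size selection that lost longer RNA would lower fragment-like 23-24 nt tags too, but their median log2 ratio was −0.20 (−0.19 with counts under 3 set to 3, against a bound of −2.22 for the others). Reads of an organism found mainly in wild type would be scarce in rdr6, as the bacterial-type 5S rRNA end was, at 0.0424 times wild type. But 94.9% of the lower tags chosen on wild-type and rdr2 reads alone (91.3% to 97.4%) stood there at 0.5 times the wild-type level or more. An organism in both wild type and rdr6 but scarce in rdr2 is not tested this way. The 5S rRNA end itself stood at 5459 RPM in rdr6 and 272 RPM in rdr2. A need for RDR2 in making the lower 23-24 nt tags remains as a hypothesis. So does any other difference between these libraries, such as a culture or library effect on siRNAs alone.

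The fall of 20-22 nt tags in rdr6 was set against the explanations that apply to it. Depth or dilution would lower other 20-22 nt tags alike, but their median log2 ratio was 0.93 for those not fragment-like and 0.39 with fragment-like tags kept, though by the rule of size 1887 of the latter were lower and 841 higher. Of the lower tags chosen on wild-type and rdr6 reads alone, 81.7% (74.99% to 87.2%) stood in rdr2 at 0.5 times the wild-type level or more. An organism shared with rdr2 is not tested this way, but the share argues against an organism scarce in rdr2 as the source of most of them. The bound used for this, 50%, replaced one of 80%, which lies within the interval, and both were set after the data were seen. For the remaining tags, 31 of 169, that source may still hold. A need for RDR6 remains a hypothesis for the tags kept in rdr2, again with 1 library behind it.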

How the results depend on the processing

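Alternatives that keep only tags that are not fragment-like or keep fragment-like tags, use a fragment share of 0.2, scale to the median 21 nt tag, leave out miR535, ask for 1 RPM in 2 libraries or choose tags on wild type and the mutant alone were chosen after seeing the data. The lower 23-24 nt tags in rdr2 far outnumbered the higher ones under each alternative run. In rdr6 the balance of lower and higher tags changed sides in both length classes. Higher tags led in the main run, with 244 lower and 431 higher at 20-22 nt. Lower tags led per moss miRNA read (427 and 48), scaled to the median 21 nt tag, and with fragment-like tags kept. The 20-22 nt balance in rdr2 turned with fragment-like tags kept. Below, ratios are to wild type and, for a change of direction, the cause was not tested unless stated. The total of 21 nt reads in rdr6 turned per moss miRNA read, though not with miR535 left out of the denominator alone. That of 23-24 nt reads in rdr6 turned when tags not fragment-like were counted alone. Scaling to the median 21 nt tag cannot test the direction of 21 nt reads, as the scale comes from that class. Genome-matched denominators, uniquely placed reads, wider windows and all TAS3 alternatives were not run, as no genome was used. No paired analysis was possible because there was 1 library per genotype. Depth limits tags near 30 reads, where even absence in a mutant can miss the 4-fold rule.

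For 23-24 nt reads the ratio was, in rdr2 and rdr6, 0.851 and 0.281 per moss miRNA read, 0.938 and 0.748 per such read without miR535, 0.691 and 0.808 with tags seen once left out, 0.755 and 0.849 for 22-24 nt, 0.540 and 1.37 (reversed) for tags not fragment-like, and 0.458 and 0.403 scaled to the median 21 nt tag. For 21 nt reads it was 1.54 and 0.633 (reversed, as miR535 dominates that denominator) per moss miRNA read. It was 1.70 and 1.69 with miR535 left out of that denominator but kept among the reads counted. It was 1.09 and 1.45 for 20-22 nt, 1.47 and 2.41 for tags not fragment-like, and 0.827 and 0.910 (both reversed) scaled to the median 21 nt tag. With tags seen once left out it was 1.264 in rdr2. For moss miRNA reads it was 0.807 and 2.94 with tags seen once left out, 0.823 and 3.04 with no mismatch, 0.741 and 1.13 without miR535, and 0.538 and 1.44 scaled to the median 21 nt tag. With no mismatch, flowering plant miRNA reads stood at 0 RPM in wild type, 2.82 in rdr2 and 0.108 in rdr6, and miR533 in rdr6 turned to 0.637.

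Counts of tags follow; those within 1.5 times the main count are mostly left out. With at least 100 reads, where fewer tags were tested, rdr2 had 213 lower and 3 higher 23-24 nt tags and 33 lower and 136 higher 20-22 nt tags, and rdr6 had 13 and 30, then 114 and 196. With the 2-fold rule, rdr2 had 752 lower and 39 higher 23-24 nt tags and 241 lower and 709 higher 20-22 nt tags, and rdr6 had 39 and 492, then 333 and 939. With fragment-like tags kept, rdr2 had 2818 lower and 719 higher 23-24 nt tags and 2016 and 1227 of 20-22 nt, and rdr6 had 1356 and 554, then 1887 and 841. With a fragment share of 0.2, rdr2 had 1244 lower and 54 higher 23-24 nt tags and 237 lower 20-22 nt tags, and rdr6 had 79 lower and 241 higher 23-24 nt tags. Per moss miRNA read, rdr6 had 66 lower and 5 higher 23-24 nt tags and 427 lower and 48 higher 20-22 nt tags. Scaled to the median 21 nt tag, rdr2 had 7 higher 23-24 nt tags and 160 lower and 162 higher 20-22 nt tags, and rdr6 had 42 lower and 18 higher 23-24 nt and 108 higher 20-22 nt tags. With 1 RPM in at least 2 libraries, rdr2 had 10 higher 23-24 nt and 181 higher 20-22 nt tags, and rdr6 53 higher 23-24 nt tags. With 30 reads in wild type and the mutant together, where fewer tags were tested, rdr2 had 237 lower 23-24 nt and 51 lower 20-22 nt tags.

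Among 128 values of named families and tags under other settings, 44 stayed within the counting interval, 83 moved beyond it, and 1, miR533 above, reversed in that a family called higher or lower changed sides. Of the 83, 7 also crossed a ratio of 1, all in families without a call. Scaled to the median 21 nt tag, miR156 (1.17 to 0.772), miR160 (1.27 to 0.837) and miR534 (1.01 to 0.663) did so in rdr2, and miR319 (1.03 to 0.491), miR529 (1.49 to 0.711) and miR536 (1.14 to 0.545) in rdr6. With no mismatch, miR533 did so in rdr2 (1.58 to 0.671).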

Other observations

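The 23-24 nt tags of wild type recurred in rdr6 and hardly in rdr2. Of the 22038 tags of 23-24 nt with at least 2 reads in wild type that were not fragment-like by wild-type reads alone, 50.3% were seen in rdr6 (49.7% to 51.0%) and 7.21% in rdr2 (6.88% to 7.56%). For 20-22 nt tags the shares were 41.0% and 31.6%. A few 20-22 nt tags went with the longer ones: of the 69 that were lower in rdr2 than in both other libraries, 50 shared at least 15 nt with a 23-24 nt tag that was lower in the same way.

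The first base of 24 nt tags that were not fragment-like was A in 31.4% of wild-type, 26.6% of rdr2 and 36.4% of rdr6 distinct tags, and C in 21.6%, 23.2% and 13.8%. In 30000 distinct tags drawn per library, 1.003% of 23 nt tags in wild type (0.894% to 1.12%) had a complementary partner offset by 2 nt at the 3′ ends, as siRNA duplexes have, against 0.253% in rdr2 (0.1996% to 0.317%) and 1.86% in rdr6. The opposite offset gave 0.723%, 0.0400% and 1.24%. For 21 nt tags the shares were 0.690%, 1.07% and 0.520% in the drawn tags and 1.47%, 1.60% and 1.44% over all distinct tags, of which the libraries held different numbers, so no difference is read from them. Over all distinct 23 nt tags, which numbered 65916, 35237 and 77058, the shares were 2.27%, 0.267% and 4.49%. The draw of 30000 took a larger part of the rdr2 tags than of the others. Drawn shares are therefore not fully comparable between libraries either, though the order of the 3 libraries was the same in both counts at 23 nt.

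Abundant 21 nt tags outside the miRNA list, chosen after their values were seen, also differed. TGGCATTGTAGGTTTAAGAGC stood at 11983 RPM in wild type, 23122 RPM in rdr2 and 2563 RPM in rdr6, 4.67-fold lower in rdr6 than in wild type. CGGCATTGTGGACCTAAGACC stood at 12558, 31468 and 12911 RPM. TGGCTGAGTCGAAGGTTGTGC rose to 8.17 times wild type in rdr6. The miR535 form TGACAACGAGAGAGAGCCCGC amounted to 0.121% of the main miR535 tag in wild type, 0.119% in rdr2 and 0.726% in rdr6 (0.713% to 0.739%).

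A hypothesis formed from the data was that the 142 nt region with fewer reads in rdr6 is cut in a single register of 21 nt, as phased siRNAs are. The register of the leading tag held 36.1% of the 21-22 nt wild-type reads, against 4.76% for an even spread, and random placements of the same tags gave a median of 25.3%, with the observed share at their 93.7th percentile. With the tags that overlap the leading tag left out, a different register held the most reads, 62.5% in wild type and 64.8% in rdr2, against a random median of 53.8% and at the 97.4th percentile. As the 2 registers differ, a single 21 nt register over the region was not borne out, and a register within each block stays open. Both blocks include many 22 nt reads, and cutting in steps of mixed length was not tested.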
